A study of Caenorhabditis elegans with 22 samples.

How the data were processed

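RNA was measured by sequencing in whole adult Caenorhabditis elegans of the wild-type strain N2 and of strains carrying the alleles ser-5(vq1) or ser-7(vq2). Per the labels' protocols, the animals were kept in liquid culture on killed bacteria, were sterilised with 0.12 mM FUDR as L4 larvae, received 5 mM serotonin in water or 50 µM loxapine in DMSO from day 1 of adulthood and were harvested 72 h later. The DMSO concentration was kept under 0.3%, and the libraries were sequenced as single reads of 100 nucleotides with 6 libraries per lane, per the labels' protocols. The authors deposited 1 table of read counts per gene and library, and these deposited counts were integers with no scaling. The aligner, the counting program and the genome build behind the counts are not given in the sources used here.

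The table held 19598 genes and 22 libraries. All 19598 identifiers were found in Ensembl release 115 as protein-coding genes, and 19578 were found in the table of gene names. Of the symbols in the table, 11 had turned into dates and were replaced through the identifiers. Chromosome positions are those of Ensembl release 115 on the WBcel235 assembly and were joined by identifier. The total count per library lay between 25652111 and 39765014.

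Groups were taken from genotype and treatment. The designs, the tests, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined, except where a later choice is stated. In R 4.3.3, edgeR 4.0.16 kept genes by its filter for expression (minimum count 10, minimum total 15), which left 16431 genes, scaled the libraries by TMM, and fitted a robust quasi-likelihood model with 1 mean per group over all 7 groups. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences between strains in the response to a compound were tested as interaction contrasts of the same model. Standard errors of log2 fold changes were taken as the fold change over the square root of F. Levels are CPM (edgeR, the count relative to the TMM-scaled library total) with the SD between libraries, except those of ser-5, ser-7 and tph-1 by group, which are plain CPM. A level of 0 was given a floor of 3 counts over the group, and intervals are exact Poisson 95% intervals. Intervals and floors cover counting error only.

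Gene lists numbered 60, of which 59 had at least 3 tested members and 1 had no member in the table. They were tested against the other genes with limma 3.58.1 (camera with a preset correlation of 0.01, and again with an estimated correlation) and without such a comparison by fry, whose p tests whether a list's genes move, on balance, one way. List p-values were adjusted over the 59 lists of a comparison. The level of a list in a library is the mean over its tested members of the log2 CPM (prior count 2) minus the mean of N2 with DMSO.

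Named genes follow a fixed rule. In the 4 comparisons of a compound with DMSO they are up to 8 genes raised and 8 lowered with the largest fold changes, among those past the threshold with a mean log2 CPM of at least 2 and no overlap between treated and control libraries. In the other 5 comparisons they are up to 5 higher and 5 lower by the same rank. Added in each are up to 3 members of each list past the threshold and a fixed set of genes of serotonin signalling and fat metabolism. A gene outside this rule is named as chosen after its values were seen.

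The alternatives were DESeq2 1.42.0 with its Wald test, the RLE size factors, no filter on low counts, a fit of the compared groups only, a replicate block, a library series block, subsets of the N2 libraries with DMSO, and leaving out each library. The replicate block uses the batch tag of the labels. This tag pairs the libraries by the labels. Tags r4, r5 and r6 each belong to a single library, of N2 with DMSO. The replicate block therefore leaves these controls without weight in any comparison. In a check of the deviations from the group means, the 51 pairs of libraries with the same tag in different groups had correlations from -0.0959 to 0.648 (median 0.230), and 38 lay over 0.1. The library series is a grouping by consecutive library numbers in the labels. Pairs from the same series had a median correlation of 0.247 (68 pairs) and pairs from different series one of -0.130 (137 pairs). Controls shared by serotonin and loxapine were treated with 20 simulations of unchanged groups, with the overlap of independent lists and with split controls.

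The pipeline was tested on simulated data built from the real means and library sizes, over the genes each simulated comparison tested. The changed genes were drawn from those with a mean log2 CPM of at least 2, so the shares do not cover lower genes. The simulated libraries were independent, without near-duplicate controls or correlation within a series, so the shares and false calls may be optimistic for the real data. For serotonin in N2 (16095 genes) it recovered 30% of the genes changed by 0.5 on the log2 scale, 86.25% of those changed by 1 and 97.5% of those changed by 2. For loxapine in ser-5 (16089 genes) the shares were 13.75%, 76.25% and 97.5%. For the strain difference in the serotonin response (16095 genes) they were 5%, 55% and 90%, and for that in the loxapine response (16118 genes) 1.25%, 48.75% and 95%. The false calls in these simulations numbered 8, 4, 6 and 7 in that order. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.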

Results

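Gene expression was measured in 22 libraries of whole C. elegans adults. It was asked how serotonin and loxapine, a tricyclic antipsychotic drug, act on N2 and on mutants of the serotonin receptor genes ser-5 and ser-7. N2 animals gave 5 libraries with DMSO, 3 with serotonin and 3 with loxapine. The ser-7 mutant gave 3 libraries with DMSO and 3 with serotonin, and the ser-5 mutant gave 3 with DMSO and 2 with loxapine. Total counts per library were 29844987 to 38691188 for N2 with DMSO, 31371456 to 39615466 with serotonin and 29369955 to 37918172 with loxapine. They were 31651301 to 38357666 and 27717696 to 38737731 for ser-7 with DMSO and serotonin, and 25652111 to 39765014 and 31286699 to 32103442 for ser-5 with DMSO and loxapine. The labels do not say whether replicates were separate cultures, so p-values measure the spread between samples. Serotonin was given in water, and the group without compound was DMSO for both compounds. The sources do not say whether the serotonin cultures also received DMSO. Comparisons of serotonin with DMSO or with loxapine may therefore include a difference in vehicle, which was not tested. The N2 DMSO replicates 2 and 5, and 3 and 6, differed from each other less than other replicates. Their chi-square per degree of freedom was 5.16 and 4.03, against 12.58 to 151 in the remaining pairs within a group. These near-duplicate controls were kept as separate libraries, so p-values, SEs and SDs that use them may be too small. The counting of strand and of reads shared by paralogs is not given, so values of gene families such as cyp-35 and of overlapping genes are uncertain to that extent.

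The receptor transcripts matched the strain labels. The ser-7 transcript (chromosome X, 2673572 to 2682384) stood at 2.47 ± 0.359 CPM in N2 with DMSO (SD, n = 5). In the 6 ser-7 libraries it gave 2 counts, or 0.00971 CPM (95% interval 0.00118 to 0.0351), all of them in the DMSO group, and the 0 counts with serotonin allow up to 0.0303 CPM over that group. The ser-5 transcript (chromosome I, 8384931 to 8387039) stood at 1.80 ± 0.387 CPM in N2 with DMSO (SD, n = 5), at 0.297 ± 0.157 CPM in ser-5 with DMSO (SD, n = 3) and at 0.429 ± 0.342 CPM in ser-5 with loxapine (SD, n = 2). The ser-5 gene was the only call between ser-5 and N2 in DMSO by edgeR, with a log2 fold change of -2.58 ± 0.35 (SE) and adjusted p = 0.00451. This call ended without ser-5 DMSO replicate 1 (adjusted p = 0.147) or 3 (0.0883), with the compared groups only (0.0913) and with N2 DMSO replicates 4 to 6 only (0.0556), over a range of 1.67e-08 to 0.147. The tph-1 transcript, which encodes the tryptophan hydroxylase of serotonin synthesis, lay between 0.540 CPM in N2 with DMSO and 0.962 CPM in ser-7 with serotonin.

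**Figure D1:**
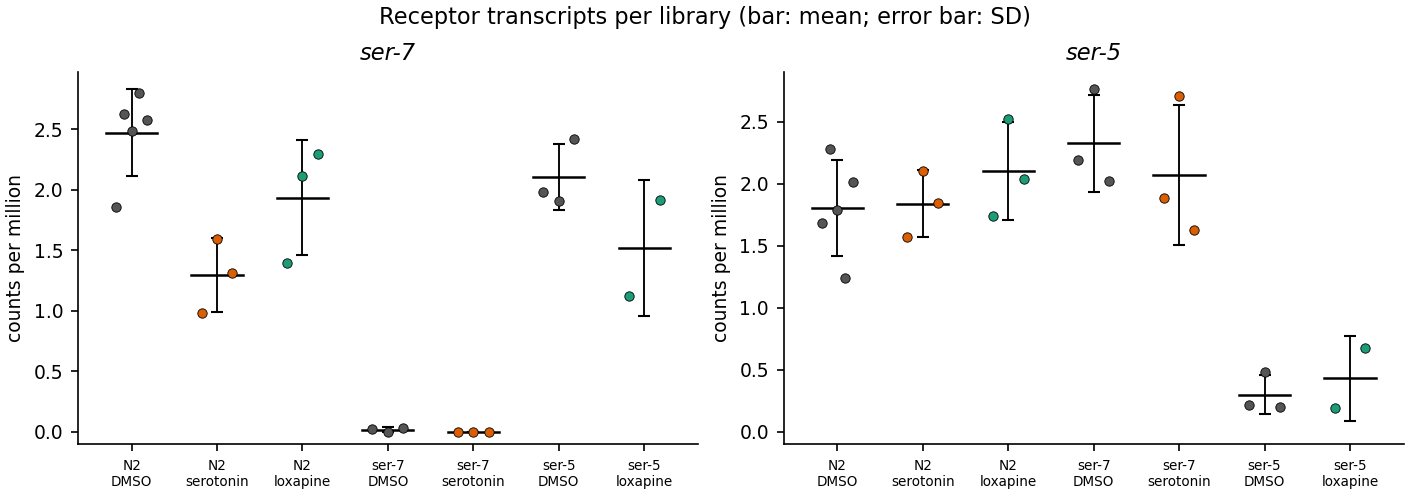
Plain CPM of ser-7 and ser-5 in each library (points), by group, with group means and SD. The ser-7 libraries hold 2 counts of ser-7 in all, and ser-5 stays detectable in its mutant at 0.297 CPM with DMSO and 0.429 CPM with loxapine.

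Serotonin in N2 raised genes of the germline and oocytes. Of 28 oocyte and eggshell genes, 25 rose and 1 fell, the same numbers as adjusted over the list alone, and the median log2 fold change was 0.81. The eggshell proteoglycan gene cpg-3 rose by 1.38 ± 0.16 (SE, adjusted p = 1.2e-05), puf-3, for an RNA-binding protein of oocytes, rose by 0.89 ± 0.12, and meg-1, for a P granule protein, rose by 0.87 ± 0.11. Of 36 germline genes, 31 rose and none fell, with 31 adjusted over the list alone. Among them were mex-3, for an RNA-binding protein (0.61 ± 0.09), and him-8, needed for pairing of the X chromosome in meiosis (0.81 ± 0.13). Of 40 genes of DNA replication and the cell cycle, 31 rose (35 adjusted over the list alone), including mcm-3 of the replicative helicase (0.65 ± 0.10) and the cyclin B gene cyb-2.2 (0.80 ± 0.12). Of 24 DNA damage response genes, 20 rose, also 20 adjusted over the list alone, including the checkpoint gene hus-1 (0.74 ± 0.12). Of 32 proteasome subunit genes, 28 rose (30 adjusted over the list alone), including rpn-7 (0.56 ± 0.11). The proteasome list averaged 0.14, 0.29 and 0.68 in serotonin replicates 1, 2 and 3, and rpn-7 rose by 0.345 without replicate 3. In the same order the oocyte list averaged 0.36, 0.68 and 1.05, and the germline list 0.18, 0.54 and 0.74. The DNA replication list averaged 0.20, 0.40 and 0.65. The highest N2 library with DMSO stood at 0.13 in the oocyte list, and at 0.12 in the germline and DNA replication lists. All 5 lists passed camera with the preset correlation. The oocyte, germline and DNA damage lists had adjusted p = 0.309 with an estimated correlation, DNA replication had adjusted p = 0.555 with an estimated correlation, and the proteasome had adjusted p = 0.573 with an estimated correlation.

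Genes of muscle, pharynx and neurons fell with serotonin in N2. Of 28 body wall muscle genes, 22 fell and 1 rose (22 and 2 adjusted over the list alone). The thin filament gene unc-87 (chromosome I, 6761221 to 6767797) went from 279 ± 17.2 to 144 ± 24.5 CPM (SD), a log2 fold change of -0.96 ± 0.11. The troponin C gene pat-10 fell by 0.84 ± 0.12 and the twitchin gene unc-22 fell by 0.75 ± 0.10. Of 65 neuropeptide genes, 53 fell and none rose (56 and none adjusted over the list alone). Examples were flp-10 (-1.02 ± 0.12), flp-27 (-1.19 ± 0.15) and nlp-14 (-0.83 ± 0.11). The neuropeptide processing genes egl-3, for a proprotein convertase, and sbt-1, for its chaperone, fell by 0.78 ± 0.12 and fell by 0.73 ± 0.09. Of 29 neuronal genes, 17 fell and 2 rose (19 and 2 adjusted over the list alone), and the choline acetyltransferase gene cha-1 fell by 1.12 ± 0.24. Of 78 pharyngeal genes, 34 fell and 4 rose (36 and 5 adjusted over the list alone), and phat-2, a gland gene, fell by 1.67 ± 0.24. Each of these 4 lists passed camera and had adjusted p = 0.309 with an estimated correlation.

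Genes of defence, of secreted peptides and of the cuticle also fell with serotonin in N2. Of 47 antimicrobial peptide genes, 23 fell and none rose, also 23 adjusted over the list alone (adjusted p = 0.309 with an estimated correlation). The caenacin gene cnc-2 went from 48.7 ± 3.90 to 16.6 ± 1.63 CPM (SD), and cnc-7 fell by 1.26 ± 0.21. Of 37 lysozyme and saposin genes, 10 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 0.720 with an estimated correlation). The invertebrate lysozyme gene ilys-3 (chromosome IV, 2464456 to 2465443) went from 29.1 ± 8.06 to 1.6 ± 1.08 CPM (SD), a log2 fold change of -4.2 ± 0.46 (adjusted p = 1.4e-05), and its neighbour ilys-2 (chromosome IV, 2467678 to 2468879) fell by 3.59 ± 0.60. Of 37 insulin-like peptide genes, 13 fell and 1 rose, the same as adjusted over the list alone (adjusted p = 0.573 with an estimated correlation), and ins-11 fell by 1.56 ± 0.29. Of 148 collagen genes, 46 fell and 1 rose (45 and 1 adjusted over the list alone, adjusted p = 0.629 with an estimated correlation), col-77 by a log2 fold change of -2.51 ± 0.47. Of 216 nuclear hormone receptor genes, 55 fell and 7 rose (47 and 6 adjusted over the list alone, adjusted p = 0.741 with an estimated correlation).

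Several genes of fat metabolism fell with serotonin in N2. The fatty acid desaturase gene fat-5 (chromosome V, 17725004 to 17726818) went from 170 ± 14.8 to 53.5 ± 13.9 CPM (SD, n = 5 and n = 3), a log2 fold change of -1.67 ± 0.18 with adjusted p = 8.1e-06 by edgeR. The diacylglycerol acyltransferase gene dgat-2 (chromosome V, 17660303 to 17661810) fell by 0.92 ± 0.15. Of 24 lipase genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation), including lips-15 (-1.44 ± 0.18) and lipl-7 (-0.62 ± 0.10). Of 15 fatty acid and retinol binding genes, 8 fell and 3 rose (9 and 3 adjusted over the list alone, adjusted p = 0.557 with an estimated correlation). Among them far-6 went from 445 ± 41.0 to 170 ± 36.5 CPM (SD), and lbp-2 fell by 1.16 ± 0.15. The triglyceride lipase gene atgl-1 rose by 0.34 ± 0.10 (adjusted p = 0.0087), a call that ended without N2 serotonin replicate 3 (0.0828) and with DMSO replicates 2 and 3 only (0.0739), over a range of 0.00113 to 0.0828. The lysosomal lipase gene lipl-4 fell by 0.81 ± 0.28 (adjusted p = 0.029). Its call ended with the replicate block (0.239), with DMSO replicates 2 and 3 only (0.299), and without DMSO replicate 4 (0.0821) or serotonin replicates 2 (0.0943) or 3 (0.0758), over a range of 0.0167 to 0.299. The genes acs-2 (0.72, adjusted p = 0.16), fat-6 (-0.16, 0.18), fat-7 (-0.27, 0.47) and dhs-3 (-0.05, 0.88) did not pass. With the library series block acs-2 did, at adjusted p = 0.0113 in a range of 0.0113 to 0.550.

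The genes with the largest rises in N2 with serotonin included the aspartyl protease gene asp-12 (chromosome V, 8269210 to 8272056), which stood at 21.8 ± 1.45 CPM with DMSO and 197 ± 187 CPM with serotonin (SD), a log2 fold change of 3.18 ± 0.43 (adjusted p = 7.15e-05) that was 2.08 without serotonin replicate 3. The pathogen-response gene dod-24 rose by 2.19 ± 0.27 and the cytochrome P450 gene cyp-35C1 by 2.13 ± 0.28. The ser-7 transcript fell by 0.87 ± 0.26 (adjusted p = 0.013). That call ended with the replicate block (0.123), with DMSO replicates 2 and 3 only (0.133) and without serotonin replicate 1 (0.0587), over a range of 0.005 to 0.133. The genes tph-1 (0.14, adjusted p = 0.75) and ser-5 (0.09, 0.83) did not pass. In all, 6102 of 16431 tested genes changed, 3346 higher and 2756 lower, and 289 and 738 of these by more than 2-fold. Lower calls outnumbered higher ones with no filter on low counts (3066 and 2632), with the compared groups only (2484 and 2143) and with the library series block (3948 and 3711). The count was 3897 without N2 serotonin replicate 3, 3509 with DMSO replicates 2 and 3 only and 4860 with the near-duplicate controls summed.

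**Figure D2:**
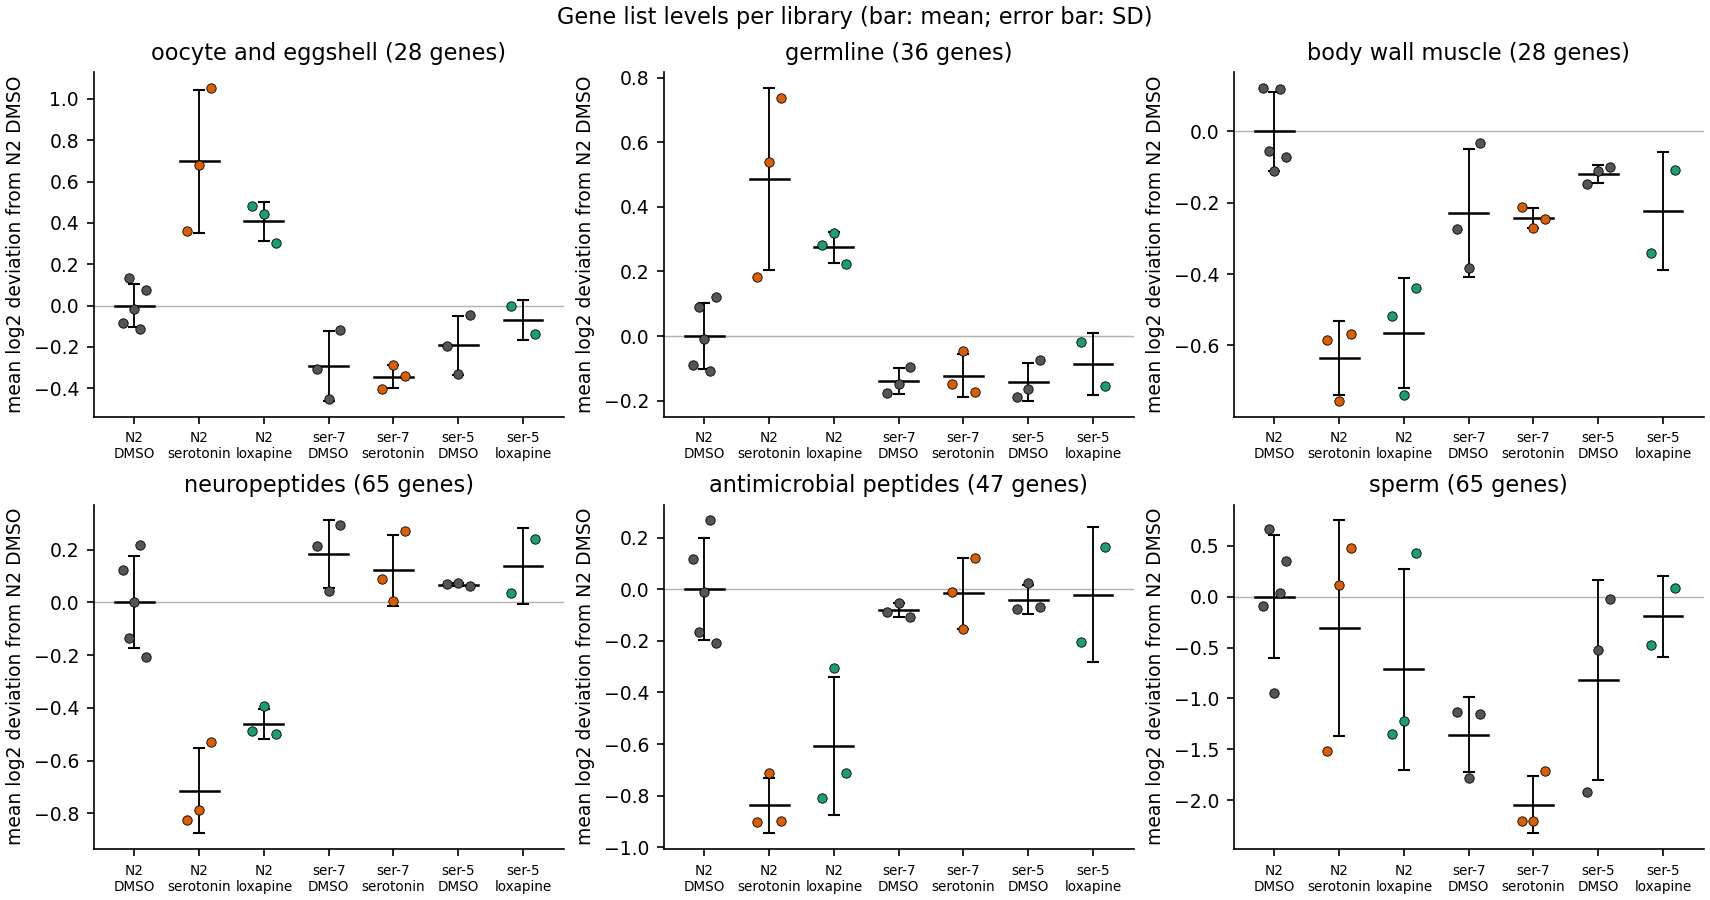
Mean log2 deviation of 6 gene lists from N2 with DMSO in each library (points), by group, with the group mean and SD. With serotonin in N2 the oocyte and eggshell list averages 0.70 and the body wall muscle list -0.64, and in ser-7 with serotonin they average -0.34 and -0.24.

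Loxapine in N2 raised genes of the cyp-35 family of cytochrome P450 enzymes, which act on foreign compounds. The gene cyp-35B3 (chromosome V, 3945353 to 3947044) had 0 to 6 counts per library with DMSO and 1008 to 1837 with loxapine, or 0.0685 ± 0.0719 and 40.9 ± 14.9 CPM (SD, n = 5 and n = 3, adjusted p = 1.5e-10). Its neighbour cyp-35B2 (chromosome V, 3942160 to 3944523) went from 1.72 ± 1.79 to 283 ± 86.6 CPM, and cyp-35B1 (chromosome V, 3939032 to 3941237) from 22.3 ± 9.92 to 134 ± 29.4 CPM. Also higher were cyp-35A1 (5.88 ± 0.59 on the log2 scale), cyp-35C1 (2.04 ± 0.28) and cyp-35A2 (1.56 ± 0.26). Of 74 cytochrome P450 genes, 19 rose and 1 fell, the same as adjusted over the list alone (adjusted p = 0.512 with an estimated correlation). The genes dod-24 and C32H11.4 rose by 2.63 ± 0.27 and 1.81 ± 0.18.

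Loxapine in N2 also raised some peroxisomal, ubiquitin adaptor and fat storage genes, where 1724 of all 16431 tested genes rose. Of 26 peroxisomal beta-oxidation genes, 5 rose, also 5 adjusted over the list alone (adjusted p = 0.757 with an estimated correlation, and not past the threshold by fry). They included the acyl-CoA oxidase genes F08A8.2 (1.36 ± 0.23) and C48B4.1 (0.94 ± 0.15) and the transporter gene pmp-5 (1.06 ± 0.17). Of 355 F-box, MATH and BATH genes, 53 rose and 11 fell, the same as adjusted over the list alone (adjusted p = 0.512 with an estimated correlation), and fbxc-47 and fbxc-32 rose by 0.85 ± 0.15 and 0.81 ± 0.13. Of 19 genes of triglyceride synthesis and lipid droplets, 7 rose and none fell (12 adjusted over the list alone, adjusted p = 0.512 with an estimated correlation). The desaturase gene fat-5 fell by 0.66 ± 0.17 (adjusted p = 0.015), to 108 ± 14.3 CPM. That call ended with the replicate block (0.0534), with DMSO replicates 2 and 3 only (0.126), with the near-duplicate controls summed (0.0550), with N2 matched to the ser-5 design (0.142) and without loxapine replicate 3 (0.0703), over a range of 0.00313 to 0.142. Not past the threshold were dgat-2 (-0.30, adjusted p = 0.15), fat-6 (0.25, 0.066), fat-7 (-0.50, 0.22), acs-2 (-0.41, 0.51), dhs-3 (0.56, 0.091), atgl-1 (0.04, 0.82), lipl-4 (-0.15, 0.74), tph-1 (0.69, 0.11), ser-7 (-0.44, 0.23) and ser-5 (0.14, 0.76). Without loxapine replicate 1, fat-6 (0.0428, range 0.0247 to 0.429) and dhs-3 (0.0230, range 0.0177 to 0.492) passed.

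Loxapine lowered muscle, neuropeptide and defence genes in N2 and raised oocyte genes. Of 28 body wall muscle genes, 21 fell and none rose (22 adjusted over the list alone), including the paramyosin gene unc-15, from 617 ± 71.7 to 300.5 ± 71.4 CPM (SD), unc-22 (-0.76 ± 0.10) and the troponin T gene mup-2 (-0.73 ± 0.14). Of 65 neuropeptide genes, 33 fell and 2 rose (44 and 2 adjusted over the list alone), with flp-3 at -0.99 ± 0.15 and nlp-15 at -0.88 ± 0.13. Of 29 neuronal genes, 9 fell, also 9 adjusted over the list alone, and the vesicular glutamate transporter gene eat-4 fell by 1.46 ± 0.24. Of 47 antimicrobial peptide genes, 10 fell (12 adjusted over the list alone), with cnc-2 at -0.87 ± 0.16. Of 28 oocyte and eggshell genes, 20 rose and 1 fell (23 and 1 adjusted over the list alone), with cpg-3 at 0.86 ± 0.16 and egg-2, for an egg surface protein, at 0.69 ± 0.13. Of 36 germline genes, 10 rose (13 adjusted over the list alone), and of 24 DNA damage genes, 9 rose and 1 fell (14 and 1 adjusted over the list alone). Of 148 collagen genes, 22 fell and 1 rose (5 and none adjusted over the list alone). Each of these 8 lists passed camera. With an estimated correlation each had adjusted p = 0.512. Of 40 DNA replication genes, 12 rose, also 12 adjusted over the list alone (adjusted p = 0.7098 with an estimated correlation). Of 83 ribosomal protein genes, 5 fell (none adjusted over the list alone, adjusted p = 0.719 with an estimated correlation), a lower share than of all genes (1377 of 16431). Neither of these lists passed fry. The largest falls included ilys-3 (-2.80 ± 0.42), the C-type lectin gene clec-86 (-2.12 ± 0.34) and ins-11 (-1.83 ± 0.29).

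In all, 3101 genes changed with loxapine in N2, 1724 higher and 1377 lower, and 175 and 313 of these by more than 2-fold. Lower calls outnumbered higher ones with no filter on low counts (1421 and 1397), with the replicate block (1567 and 1463), with the library series block (2753 and 2522) and without loxapine replicate 1 (1826 and 1625) or 2 (320.0 and 236). They also did with DMSO replicates 2 and 3 only (197 and 142) and with N2 matched to the ser-5 design (76 and 52). The count was 1759 without N2 DMSO replicate 2, 1779 without DMSO replicate 5, 556 without loxapine replicate 2 and 1618 without loxapine replicate 3. It was 339 with DMSO replicates 2 and 3 only, 1120 with replicates 4 to 6 only, 1129 with the near-duplicate controls summed, 128 with N2 matched to the ser-5 design and 5275 with the library series block. The calls of cpg-3 (adjusted p = 0.0595, range 0.00019 to 0.0595) and egg-2 (0.0522, range 0.000377 to 0.0522) ended with DMSO replicates 2 and 3 only, and that of cnc-2 (0.0529, range 8.27e-05 to 0.0529) with N2 matched to the ser-5 design.

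Serotonin and loxapine changed overlapping sets of genes in N2. Both raised 1521 genes and both lowered 875, against 351 and 231 for independent lists, and 6 genes moved in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had r = 0.647, against a mean of 0.364 in 20 simulations with unchanged groups against the same controls. Deviations from the group means were also correlated between the serotonin and loxapine libraries of a batch tag (0.648, 0.271 and 0.414), which neither the simulations nor the splits of the controls include, so the excess over 0.364 is not all attributed to a shared response. The covariance was 0.207 against 0.0371 simulated, a difference of 0.170. The simulations drew the controls as independent libraries, although N2 DMSO replicates 2 and 5, and 3 and 6, were near-duplicates. The simulated r, covariance and share of the same sign may therefore be too low. The same sign was seen for 79.8% of genes, against 62.1% simulated. The simulations gave 0 shared calls, which unchanged groups would give in any case, so this is no measure of the excess. When the controls were split between the compounds, the shared calls were 512 higher and 328 lower (73.6 and 47.7 for independent lists, r = 0.569) in the first split. They were 112 and 149 (23.8 and 25.5 for independent lists, r = 0.530) in the other. The splits parted N2 DMSO replicates 2 and 3 from 4 to 6, where 5 and 6 are their near-duplicates. They therefore do not remove noise shared by the controls.

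The direct comparison of serotonin with loxapine in N2 gave higher cyp-35B genes with loxapine. With serotonin cyp-35B3 had 2 counts over the 3 libraries (0.0226 CPM), against 40.9 CPM with loxapine, and cyp-35B1 stood at 8.19 ± 1.53 against 134 ± 29.4 CPM (SD, n = 3 each). The log2 difference was -4.02 ± 0.38 for cyp-35B1 and -8.23 ± 0.75 for cyp-35B2. The genes cyp-35C1 (0.09, adjusted p = 0.905) and cyp-35A2 (-0.39, adjusted p = 0.477) did not pass. Of 74 cytochrome P450 genes, 8 were lower with serotonin and none higher (24 and 1 adjusted over the list alone, adjusted p = 0.170 with an estimated correlation). Of 15 fatty acid and retinol binding genes, 3 were lower (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.503 with an estimated correlation), and of 15 metal-response genes, 1 was lower (3 adjusted over the list alone, adjusted p = 0.149 with an estimated correlation). Of 28 oocyte and eggshell genes, none passed over all genes and 16 were higher with serotonin adjusted over the list alone (adjusted p = 0.503 with an estimated correlation). The gene asp-12 was higher with serotonin by 3.61 ± 0.53 (2.49 without serotonin replicate 3) and F49F1.1 by 1.35 ± 0.23, and the neuropeptide gene flp-8 (-1.497 ± 0.18) and the peroxisomal catalase gene ctl-2 (-0.68 ± 0.08) were lower. These 4 calls ended with the compared groups only, at adjusted p = 0.423 (range 1.84e-10 to 0.423), 0.417 (7.37e-06 to 0.417), 0.197 (1.21e-10 to 0.197) and 0.199 (4.65e-07 to 0.199) in that order. In all, 246 genes differed, 36.6% of them higher with serotonin (50.9% with RLE size factors, 57.7% by DESeq2). Without serotonin replicate 1, 1141 were higher and 296 lower, and with the compared groups only 0 were higher and 8 lower. The count was 1437, 437 and 115 without serotonin replicate 1, 2 and 3, and 911, 33 and 43 without loxapine replicate 1, 2 and 3. It was 8 with the compared groups only, 751 by DESeq2, 896 with the replicate block and 1293 with the library series block.

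In the ser-7 mutant, serotonin changed no gene past the threshold. The count was 0 by edgeR and 0 by DESeq2, and 643 and 654 genes had an unadjusted p under 0.05. The gene fat-5 stood at 149 ± 48.1 CPM with DMSO and 91.3 ± 11.6 CPM with serotonin (SD, n = 3 each), a log2 fold change of -0.71 ± 0.19 with adjusted p = 0.943. The values of dgat-2 and lipl-4 were -0.44 ± 0.16 and -0.68 ± 0.31. Of 65 sperm genes none passed, nor did any adjusted over the list alone, with a median of -0.68 (adjusted p = 0.922 with an estimated correlation). Of 38 aspartyl and cysteine protease genes none passed, nor adjusted over the list alone, with a median of -0.22 (adjusted p = 0.704 with an estimated correlation). Of 22 nucleolar genes none passed and 1 was higher adjusted over the list alone, with a median of 0.11 (adjusted p = 0.546 with an estimated correlation). With the library series block 10 genes passed, 4 higher and 6 lower. Among them was C15B12.8 (1.95 ± 0.26, adjusted p = 0.0208 by edgeR with that block), chosen after its values were seen. The 3346 genes that rose in N2 had a median log2 fold change of 0.49 there and -0.02 in ser-7, and the 2756 that fell had -0.75 and -0.06. These genes were picked by their values in N2, so the N2 medians may be too large in size. In ser-7, 42.2% of the first set and 62.5% of the second had the same sign as in N2.

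The serotonin response itself differed between ser-7 and N2. A response is here the log2 fold change with the compound. A higher response in ser-7 can thus be a smaller fall than in N2, and a lower response a smaller rise. Genes that fell with serotonin in N2 had the higher response in ser-7, among them ilys-3 (4.26 ± 0.60, adjusted p = 0.00232), cnc-2 (1.95 ± 0.24, adjusted p = 0.00038), cnc-7 (1.85 ± 0.30), lips-15 (1.54 ± 0.25), nlp-14 (0.98 ± 0.16), flp-10 (0.96 ± 0.17), egl-3 (0.85 ± 0.18) and unc-87 (0.82 ± 0.17). In ser-7 the ilys-3 transcript stood at 43.6 ± 17.0 CPM with DMSO and 45.4 ± 10.9 CPM with serotonin (SD, n = 3 each). The response was also higher for F48C1.9 (4.46 ± 0.82), the pharyngeal myosin gene myo-2 (1.99 ± 0.37) and unc-15 (1.104 ± 0.26). It was lower in ser-7 for asp-12 (-3.59 ± 0.66, and -2.49 without N2 serotonin replicate 3), dod-24 (-2.38 ± 0.42), cpg-3 (-1.45 ± 0.25), meg-1 (-0.90 ± 0.17) and hus-1 (-0.81 ± 0.18). The response of fat-5, chosen after its values were seen, was higher in ser-7 by 0.96 ± 0.26 (adjusted p = 0.018), a call that ended with DMSO replicates 2 and 3 only (0.0841, range 0.00296 to 0.0841).

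By list, the difference ran from oocytes to muscle and defence. The response was lower in ser-7 for 23 of 28 oocyte and eggshell genes (24 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation). It was lower for 17 of 36 germline genes (21 adjusted over the list alone, adjusted p = 0.552 with an estimated correlation). It was lower for 16 of 40 DNA replication genes and 9 of 32 proteasome genes (21 and 20 adjusted over the list alone), each list with adjusted p = 0.731 with an estimated correlation. It was higher for 23 of 65 neuropeptide genes (36 adjusted over the list alone, adjusted p = 0.552 with an estimated correlation) and for 13 of 47 antimicrobial peptide genes (15 adjusted over the list alone, adjusted p = 0.374 with an estimated correlation). It was higher for 11 of 28 body wall muscle genes (21 adjusted over the list alone) and for 20 of 78 pharyngeal genes, of which 2 were lower (24 and 2 adjusted over the list alone). Both of these lists had adjusted p = 0.458 with an estimated correlation. Of 24 lipase genes, 5 had the higher response (7 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation). In all, 2565 genes differed in response, 928 higher in ser-7 and 1637 lower, and 419 and 206 of these by more than 2-fold. The count was 4490 and 1203 without N2 serotonin replicate 1 and 3, and 1644 without ser-7 serotonin replicate 1. It was 490 with N2 DMSO replicates 2 and 3 only, 1595 with replicates 4 to 6 only, 1583 with the near-duplicate controls summed and 4134 with the library series block.

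**Figure D3:**
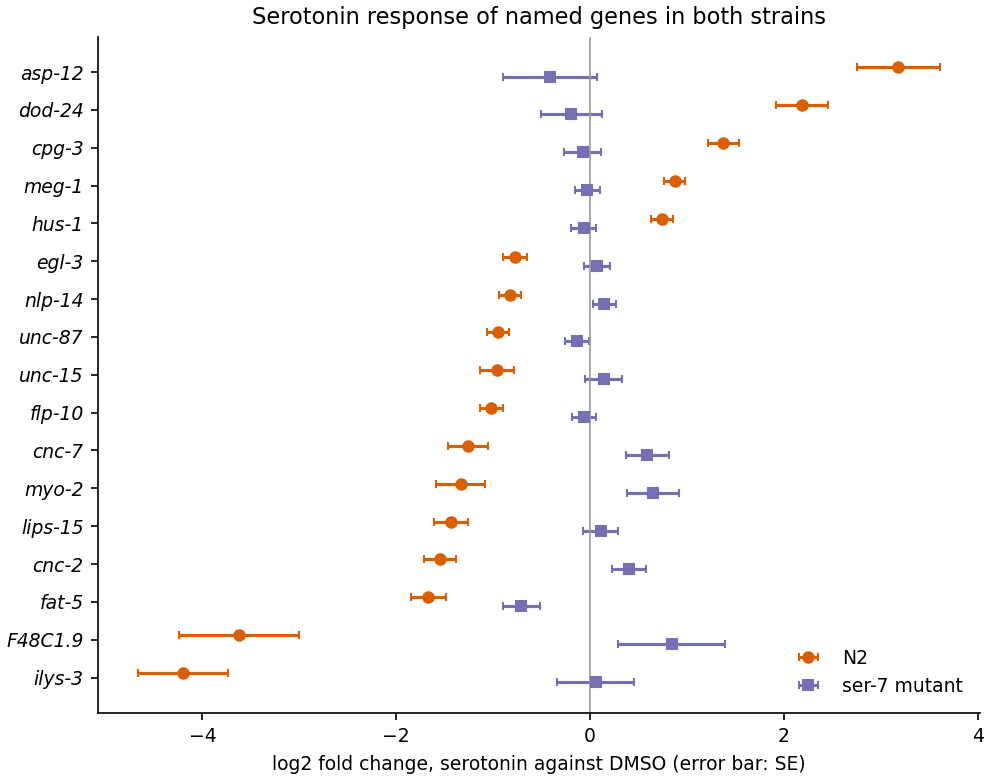
Log2 fold changes with serotonin in N2 and in ser-7 for named genes (points, with SE bars). In N2 ilys-3 lies at -4.2 and asp-12 at 3.18, and the difference between strains is 4.26 for ilys-3 and -3.59 for asp-12 (-2.49 without N2 serotonin replicate 3).

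In the ser-5 mutant, loxapine raised 8 genes, and 4 of them belong to the cyp-35 family. The gene cyp-35B3 had 0 to 2 counts per library with DMSO and 1220 to 1454 with loxapine (41.7 ± 4.59 CPM, SD, n = 2, adjusted p = 8.98e-09). The level of cyp-35B2 went from 1.75 ± 0.903 to 239 ± 8.46 CPM, and that of the drug transporter gene pgp-13 (chromosome X, 12738754 to 12744111) from 2.51 ± 0.439 to 34.3 ± 3.61 CPM. In N2, pgp-13 stood at 2.38 CPM with DMSO and 21.96 ± 5.13 CPM with loxapine. The others were cyp-35A1 (5.36 ± 0.75, adjusted p = 0.00165), cyp-35B1 (2.51 ± 0.38, 0.00814) and C32H11.4 (1.63 ± 0.23, 0.00165), and C01G12.5 (3.92 ± 0.55, 0.00165) and cyp-33C6 (2.31 ± 0.40, 0.0236), these last chosen after their values were seen. Of 74 cytochrome P450 genes, 5 rose (8 adjusted over the list alone), with a median of 0.02 and a mean of 0.41 (adjusted p = 0.777 with an estimated correlation). The median was -0.01 with the replicate block and with the library series block. Of 41 ABC transporter genes, 1 rose, also 1 adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). Of 41 histone genes none passed, nor adjusted over the list alone, with a median of 0.35 (adjusted p = 0.777 with an estimated correlation).

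The other calls in ser-5 depended on few libraries. Without loxapine replicate 1, 3 genes passed, and the adjusted p was 0.0563 for cyp-35A1 (range 2.97e-05 to 0.0662), 0.106 for C32H11.4 (range 1.04e-07 to 0.106), 0.0512 for C01G12.5 (range 6.82e-07 to 0.0662), 0.0897 for cyp-35B1 and 0.0636 for cyp-33C6. For cyp-35B1 it was also 0.0951 and 0.115 without DMSO replicate 1 and 3 and 0.0937 without loxapine replicate 2 (range 1.65e-09 to 0.115). For cyp-33C6 it was 0.0951, 0.240 and 0.199 without DMSO replicate 1, 2 and 3, 1 without loxapine replicate 2 and 0.0641 with the replicate block (range 0.00054 to 1). With the compared groups only, 5 genes passed, with cyp-35A1 and C01G12.5 at 0.0662 and cyp-33C6 at 0.203. The genes that rose with loxapine in N2 had a median log2 fold change of 0.45 there and 0.10 in ser-5, and the genes that fell had -0.65 and -0.10. They too were picked by their values in N2, so the N2 medians may be too large in size. In ser-5, 84.8% of the first set and 71.7% of the second had the same sign as in N2.

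The difference in loxapine response between ser-5 and N2 passed for no gene by edgeR, with 1561 genes at an unadjusted p under 0.05, and for 20 by DESeq2. For ilys-3, chosen after its values were seen, it was 2.28 ± 0.59 with adjusted p = 0.40, 0.00021 with the replicate block and 4.63e-06 with the library series block (range 4.63e-06 to 0.970). Of 65 neuropeptide genes none passed and 15 were higher in ser-5 adjusted over the list alone, with a median of 0.59. Of 28 body wall muscle and 47 antimicrobial peptide genes none passed and 1 each was higher adjusted over the list alone, with medians of 0.47 and 0.58. These 3 lists passed camera and had adjusted p = 0.562 with an estimated correlation. The count was 6, 1 and 1 without N2 loxapine replicate 1, N2 loxapine replicate 2 and ser-5 loxapine replicate 1, and 2 with the compared groups only. It was 1 with the replicate block and 43 with the library series block.

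**Figure D4:**
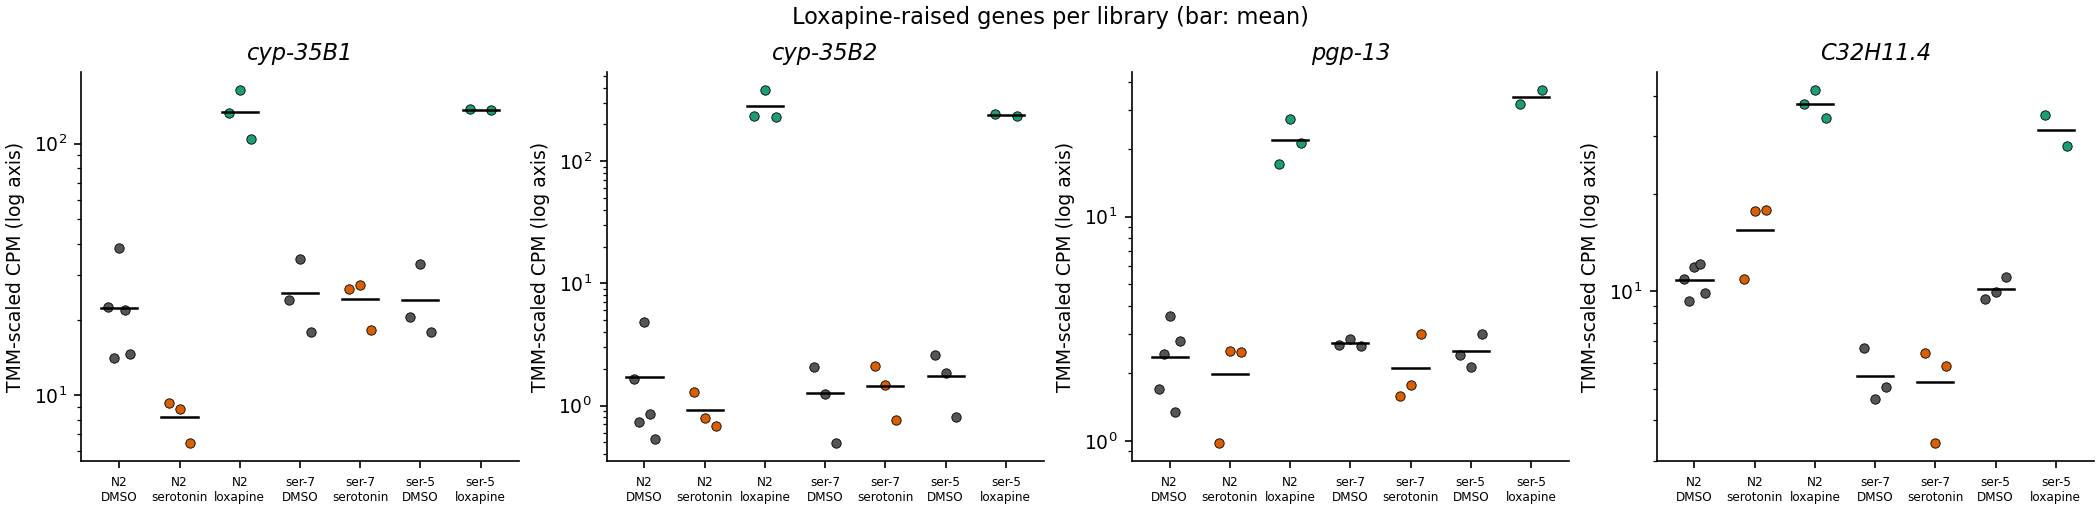
CPM (log axis) of genes raised by loxapine in ser-5, in each library (points), by group, with the group mean (bars), for cyp-35B1, cyp-35B2, pgp-13 and C32H11.4. With loxapine cyp-35B2 averages 283 CPM in N2 and 239 CPM in ser-5, against 1.72 and 1.75 CPM with DMSO.

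Without compound, the genes that were lower in ser-7 than in N2 included a few of yolk, oocytes and fatty acid synthesis. The ser-7 transcript itself was lower at adjusted p = 1.9e-07. Of 3 vitellogenin genes tested (vit-2, vit-5 and vit-6 were not analysed here), 2 were lower (3 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation), with vit-1 at -1.15 ± 0.27 from 319 ± 17.9 CPM in N2. Of 28 oocyte and eggshell genes, 3 were lower (8 adjusted over the list alone, adjusted p = 0.615 with an estimated correlation). Among them were lin-41, for a regulator of oocytes (-0.83 ± 0.14, adjusted p = 0.00853), and mex-1 (-0.66 ± 0.11, adjusted p = 0.0077). Of 30 fatty acid synthesis genes, 2 were lower (4 adjusted over the list alone, adjusted p = 0.615 with an estimated correlation), including pod-2, for acetyl-CoA carboxylase (-0.76 ± 0.13, adjusted p = 0.00824). Of 65 sperm genes, none passed and 30 were lower and 1 higher adjusted over the list alone, with a median of -1.95 (adjusted p = 0.615 with an estimated correlation). Of 22 heat shock genes none passed, and 7 were higher and 1 lower adjusted over the list alone (adjusted p = 0.615 with an estimated correlation). The gene F54F7.6 was higher by 0.98 ± 0.13 (adjusted p = 0.00145), and K10C2.1, chosen after its values were seen, was lower (-0.90 ± 0.14, adjusted p = 0.0073).

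In all, 197 genes differed between ser-7 and N2 with DMSO, 73 higher and 124 lower, and 23 and 6 of these by more than 2-fold. The count was 120, 64, 103, 116 and 70 without N2 DMSO replicate 2, 3, 4, 5 and 6, and 2 and 16 without ser-7 DMSO replicate 1 and 2. It was 3 with the replicate block (ser-7, K10C2.1 and F54F7.6), 1 with DMSO replicates 2 and 3 only, 13 with replicates 4 to 6 only, 4 with the near-duplicate controls summed, 535 by DESeq2, 369 with the compared groups only and 848 with the library series block. Without ser-7 DMSO replicate 1 the adjusted p was 0.0840 for pod-2 and lin-41 (ranges 2.8e-06 to 0.217 and 5.29e-05 to 0.217), 0.0764 for mex-1 (range 8.4e-05 to 0.217) and 0.0595 for K10C2.1 (range 4.12e-06 to 0.176). With the replicate block it was 0.0575 for pod-2, 0.0672 for lin-41 and 0.0507 for mex-1, and with the near-duplicate controls summed it was 0.0520, 0.0516 and 0.0507 in that order. With DMSO replicates 2 and 3 only it was 0.217 for these 3 genes, 0.176 for K10C2.1 and 0.176 for F54F7.6 (range 6.5e-08 to 0.176). For vit-1 (adjusted p = 0.044) it was 0.0779, 0.0953, 0.0758, 0.0654 and 0.101 without N2 DMSO replicate 2, 3, 4, 5 and 6, 0.233 and 0.226 without ser-7 DMSO replicate 1 and 2, 0.0550 with RLE size factors and 0.204 with the replicate block. It was also 0.350 with DMSO replicates 2 and 3 only, 0.185 with replicates 4 to 6 only and 0.177 with the near-duplicate controls summed (range 0.00146 to 0.350).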

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

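The gaps between gene lists within each library series and the ratio of cyp-35B2 to cyp-35B3 were tests set before their values were seen, and all other tests of explanations and splits given here were chosen only after the result was seen.

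The response to serotonin differed between ser-7 and N2 for 2565 genes by the interaction contrast of edgeR. The difference was positive for ilys-3 (4.26), F48C1.9 (4.46), cnc-2 (1.95), cnc-7 (1.85), myo-2 (1.99), unc-15 (1.104), unc-87 (0.82), lips-15 (1.54), nlp-14 (0.98), flp-10 (0.96), egl-3 (0.85) and fat-5 (0.96, chosen after its values were seen). It was negative for asp-12 (-3.59, and -2.49 without N2 serotonin replicate 3), dod-24 (-2.38), cpg-3 (-1.45), meg-1 (-0.90) and hus-1 (-0.81), all on the log2 scale. In N2 with DMSO, replicate 4 stood apart for cyp-35B2 at 4.84 CPM (0.535 to 1.65 in the others), and replicate 5 for flp-8 at 10.4 CPM (8.01 to 8.48 in the others). Such a gap appears by chance in about 1 in 20 groups of independent libraries. Of 91 items tested in this group (the library total, printed genes and printed lists), 2 showed one, where 4.55 would by chance. The near-duplicate controls are not independent, so this expected number is only rough.

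Oocyte and germline genes were higher and muscle and neuropeptide genes lower with serotonin in N2. A difference between library series is argued against by the gap between the oocyte and muscle lists, which was at least 0.848 within each of the 3 series. A smaller share of all somatic tissue in the animals would lower intestine and muscle genes alike, but the medians of the intestine and muscle lists differed by 0.63 (SE over list members 0.146). By library the gap was 0.21, 0.85 and 0.75 in serotonin replicates 1, 2 and 3 and at most 0.15 with DMSO, so replicate 1 argues against it only weakly. A response that needs SER-7 may account for the pattern, since the gap was 1.59 in N2 and -0.067 in ser-7, and separate effects on germ cells and on somatic tissues, which were not tested, stay open.

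Serotonin changed genes in N2 and none past the threshold in ser-7. The smaller number of control libraries in ser-7 is not enough to account for this, since 4853 genes still changed in N2 with 3 control libraries. With the library series as a term 4134 genes differed in response. N2 with serotonin and both ser-7 groups had a library in every series, so this count tests a difference between series only weakly. Serotonin that did not reach the ser-7 animals cannot be told apart from a response that needs SER-7. In ser-7 the genes lowered in N2 gave an unadjusted p of 0.338 by fry. By camera it was 0.00058 with the preset correlation and 0.232 with an estimated one. With the library series block 10 genes passed in ser-7, and no transcript fixed beforehand reports uptake.

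Loxapine raised cyp-35 genes and pgp-13 in ser-5. Reads shared between cyp-35B2 and cyp-35B3 as the only source of the counts of either gene would hold their ratio fixed, but it varied 2.32-fold over the 5 loxapine libraries (4.11 to 9.53 in N2, 5.45 and 6.06 in ser-5). The widest spread lay in N2, and the 2 ser-5 libraries alone do not argue against shared reads as the only source. Sharing of part of the reads stays open, and the 4 of 8 genes outside the family do not test it, since the pattern names such a gene. RNA of N2 animals with loxapine in the ser-5 libraries would need a ser-5 transcript near the N2 level, given cyp-35B3 at 102% of it, but the transcript stood at 21.2%. A loxapine response that does not need SER-5 may account for these genes, but the ser-5 transcript stayed detectable, so a lack of SER-5 is not shown. For the wider response this cannot be told apart with 2 loxapine libraries. The genes raised in N2 had a median of 0.10 in ser-5, and 84.8% had the same sign there. As a set they gave an unadjusted p of 3.7e-17 by camera with the preset correlation. It was 0.227 by camera with an estimated correlation and 0.343 by fry.

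Other splits of the compared libraries, fitted alone, took the near-duplicate controls of N2 as separate libraries. With each such pair summed, N2 has 3 controls, and 3 against 3 libraries are too few for a share under 0.05. By splits of the separate libraries the share was under 0.05 for serotonin in N2 (1 of 56 splits gave as many genes, the real one with 4627 and the highest other with 84). It was also under 0.05 for loxapine in N2 (1 of 56, with 3936 and 80). Given the near-duplicate controls, these shares alone do not exclude chance. For ser-7 against N2 in DMSO, 2 of 56 splits gave as many genes, and with the same limit this share does not exclude chance. The real split gave 369, and the highest other, 1457, put N2 DMSO replicates 3 and 6 with ser-7 DMSO replicate 3, all of the third library series, which points to a structure of the samples (848 genes with the library series block). That comparison gave 3 genes with the replicate block, 4 with the near-duplicate controls summed and 2 without ser-7 DMSO replicate 1. For ser-5 against N2 in DMSO, chance could not be excluded by the share, but the real count was 0, so all 56 of 56 splits had to give as many. The highest, 2006, lay along the same series (4 genes with the library series block). For the strain difference in the serotonin response, chance could not be excluded by the share, since 11 of 100 splits, the real one included, gave at least the real 1713 genes, the highest 6894. Of these, 10 are among the 11 splits that keep the 3 serotonin libraries of each strain together, which still hold the serotonin effect of N2 and do not test chance. Of the 89 splits that mix them, 1 gave as many genes (highest 2203, median 0). The split with 6894 joined the ser-7 serotonin libraries with the DMSO libraries of the third series, and the library series block gave 4134 genes for the real split. For serotonin in ser-7 (10 of 10 splits, real 0, highest other 1) and serotonin against loxapine in N2 (2 of 10 splits, real 8, highest other 35) the splits are too few for a share under 0.05. The batch tag pairs libraries across groups, so the real split was also compared with the splits that part as many pairs. For serotonin in N2, loxapine in N2 and ser-7 against N2 in DMSO the 15 other such splits gave 0 genes each, and for ser-5 against N2 at most 1. For serotonin in ser-7 and serotonin against loxapine the 3 other such splits gave 0. The highest counts of other splits given here for these 6 comparisons came from splits that part fewer pairs.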

How the results depend on the processing

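The near-duplicate controls summed, N2 matched to the ser-5 design, the library series block for lists and the tests of the overlap by other tools were chosen only after the data were seen. Of 123 printed gene values followed through the alternatives, 86 kept their direction and side of the threshold under every alternative, and 6 changed direction under at least 1. None of the 62 list results changed the direction of its test, and only the median of cytochrome P450 genes with loxapine in ser-5 changed sign (0.02, and -0.01 with the replicate block and with the library series block). None changed its call with either block, 58 lost it with an estimated correlation, and with fry 20 lost it and 3 gained it. Where values moved the cause was not tested.

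DESeq2 gave 20 genes for the loxapine response between ser-5 and N2, 535 for ser-7 against N2, 5 for ser-5 against N2 and 751 for serotonin against loxapine. The compared groups only gave 5 for loxapine in ser-5, 2 for the loxapine response, 369 for ser-7, 0 for ser-5 and 8 for serotonin against loxapine. The replicate block, which leaves N2 DMSO replicates 4 to 6 without weight, gave 1, 3 and 896 for the loxapine response, ser-7 against N2 and serotonin against loxapine. It moved no other count by over 1.5 times, and the printed genes whose call it changed are given beside their values. The library series block gave 5275 for loxapine in N2, 10 for serotonin in ser-7, 4134 and 43 for the serotonin and loxapine responses, 848 and 4 for ser-7 and ser-5 against N2, and 1293 for serotonin against loxapine. N2 DMSO replicates 2 and 3 only gave 3509 and 339 for serotonin and loxapine in N2, 490 for the serotonin response and 1 for ser-7 against N2. Replicates 4 to 6 only gave 1120 for loxapine in N2, 1595 for the serotonin response, and 13 and 0 for ser-7 and ser-5 against N2. The near-duplicate controls summed gave 1129 for loxapine in N2, 1583 for the serotonin response and 4 for ser-7 against N2. N2 matched to the ser-5 design gave 128 for loxapine. The overlap of serotonin and loxapine, 2396 genes, was 840 and 261 with split controls and 3901 with the library series block. The number of list tests past the threshold was 153, 0 with an estimated correlation and 65 by fry.

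Leaving out each library gave 3897 to 7249 genes for serotonin in N2, 556 to 3451 for loxapine in N2, 0 to 0 for serotonin in ser-7, 3 to 7 for loxapine in ser-5, 1203 to 4490 and 0 to 6 for the serotonin and loxapine responses, 2 to 250.0 for ser-7 against N2, 0 to 1 for ser-5 against N2 and 33 to 1437 for serotonin against loxapine. A lone remaining loxapine library in ser-5 was assumed to vary like the other groups.

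Among genes not past the threshold, with serotonin in N2, tph-1 was -0.19 without serotonin replicate 2 (0.42 without replicate 3, the highest). With DMSO replicates 2 and 3 only, ser-5 was -0.069, and leaving out a library gave -0.019 (DMSO replicate 5) to 0.22 (serotonin replicate 1). The dhs-3 value was 0.032 by DESeq2, 0.031 with RLE size factors and 0.10 with the replicate block. Leaving out DMSO replicate 3 or 6 gave 0.0092 and 0.016, and the range over libraries was -0.25 (serotonin replicate 3) to 0.21 (serotonin replicate 1). With loxapine in N2, ser-5 was -0.017 with DMSO replicates 2 and 3 only, and atgl-1 was -0.066 without loxapine replicate 1. The lipl-4 value was 0.11 with the replicate block and 0.14 with DMSO replicates 2 and 3 only, and leaving out a library gave -0.40 (loxapine replicate 2) to 0.021 (DMSO replicate 4). With loxapine in N2, dgat-2, fat-7, dhs-3 and fat-6 passed with the library series block (adjusted p = 0.0425, 0.0259, 0.0177 and 0.0275), dhs-3 also with the replicate block (0.0268), and fat-6 and tph-1 with the compared groups only (0.0247 and 0.0427). Depth limits ser-7 and ser-5, at a few CPM, and genes such as cyp-35B3 near 0 with DMSO.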

Other observations

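The tests of the sperm, vitellogenin and serotonin receptor genes given here use lists fixed before the data were examined, and the choice to describe them was made only after the result was seen.

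Sperm genes varied widely between libraries of 1 group and had their lowest group means in ser-7 (adjusted p = 0.615 with an estimated correlation for ser-7 against N2 in DMSO). On the log2 scale against N2 with DMSO, the list of 65 tested genes averaged -1.36 ± 0.37 in ser-7 with DMSO and -2.04 ± 0.28 in ser-7 with serotonin (SD, n = 3 each). It averaged -0.31 ± 1.06 in N2 with serotonin and -0.72 ± 0.99 in N2 with loxapine (SD, n = 3 each), and the 5 N2 libraries with DMSO had an SD of 0.60. It averaged -0.82 ± 0.98 in ser-5 with DMSO (SD, n = 3), where replicate 1 stood at -1.91, below every ser-7 library with DMSO (-1.78 to -1.13). Between ser-5 and N2 in DMSO none passed, nor adjusted over the list alone, with a median of -0.77 (adjusted p = 0.864 with an estimated correlation). Part of the spread followed the library series. In all N2 groups, ser-5 with DMSO and ser-7 with serotonin, series 1 was lowest and series 3 highest. The ser-7 libraries with DMSO did not follow this order, and ser-5 with loxapine had no library of series 3.

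Of the yolk protein genes, vit-1, vit-3 and vit-4 rose with serotonin in N2, and vit-2, vit-5 and vit-6 were not analysed here, so the list covers only part of the family. All 3 tested members rose, also 3 adjusted over the list alone, with a median of 0.82, and with loxapine 1 of 3 rose, also 1 adjusted over the list alone. As lists they did not pass camera (adjusted p = 0.125 and 0.0811, and 0.703 and 0.629 with an estimated correlation), and by fry they passed with serotonin (adjusted p = 0.0293) and did not with loxapine (0.0930). Of 7 serotonin receptor genes, 5 fell with serotonin in N2 (6 adjusted over the list alone) and 3 fell with loxapine (4 adjusted over the list alone), with medians of -0.61 and -0.46. As lists they did not pass camera (adjusted p = 0.0568 and 0.0621, and 0.325 and 0.512 with an estimated correlation), and they passed fry (adjusted p = 5.9e-05 and 0.0031).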
